A study of Rattus norvegicus with 6 samples.

How the data were processed

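Gene expression was measured with Illumina bead arrays, which read each transcript as the fluorescence of beads that carry one probe sequence, in liver tissue of 6 male Wistar rats. Per the labels' protocols, all 6 rats received weekly injections of diethylnitrosamine (DEN), a liver carcinogen, at 50 mg/kg for 18 weeks. In weeks 13 to 18 they also received injections of either erlotinib, an inhibitor of the epidermal growth factor receptor (EGFR) kinase, at 2 mg/kg or its vehicle on 5 days a week. Per the labels' protocols, tissue was taken in week 19, after 1 week without DEN, and RNA was extracted with TRIzol and hybridised by the standard Illumina procedure with the Cy5 label. The labels disagree on the tissue. Titles, source names and the tissue field call it hepatocellular carcinoma, whereas the treatment and extraction protocols describe liver tissue without tumour. Both descriptions remain open here, and the samples are called tissues. The labels also say that vehicle animals of separate erlotinib studies were pooled, without naming the study of each vehicle rat.

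The groups were taken from the labels: 3 arrays from rats given erlotinib and 3 from rats given vehicle. Each label carries its own animal number, so the arrays are separate animals. Replicate numbers follow accession order, serve only as names, and pair no arrays. No slide, scan date or batch was given in the sources used here, so batches could not be tested.

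The main values were the authors' deposited non-normalized intensities, on a linear scale, for 22523 probes. Per the file headers, that table pairs a probe identifier with 1 intensity for each animal. Detection p-values, bead counts and control probes were not used here, and the scanner software, background handling and summarisation are not given in the sources used here. Raw mean intensity ran from 204 to 306, the median from 94.8 to 102 and the maximum from 20979 to 23354. The authors' deposited processed intensities, also linear, served as an alternative. Set against the raw values of the same array, each of these columns had a Spearman correlation of 1 across probes. The medians of these columns were 96.1, 96.1, 96.1, 96.5, 96.1 and 96.1, in the order erlotinib 1 to 3 and vehicle 1 to 3. The normalization method behind the authors' deposited processed intensities stays unknown, while their scale is linear and their probes are not centred.

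The plan fixed before the data were examined named limma's neqc, which needs control probes or detection p-values. In their place each array's background was taken from its dim probes: the mode of the log2 density gave the background mean, 90.3 to 95.7 over the arrays, and the distance of values under the mode gave its SD, 4.09 to 4.83. Intensities were corrected with the normexp convolution at these parameters, an offset of 16 was added, and arrays were quantile normalized and log2 transformed. A detection p was the upper normal tail of that background. Probes with a detection p under 0.05 on at least 3 of 6 arrays were kept, which left 9966. Between 8956 (39.8%) and 10266 (45.6%) probes an array were above background. Because of the offset, differences of dim probes are understated.

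Of all probes, 13793 had 1 gene symbol in the platform annotation, 0 had several, and 8730 are unnamed here. Through gene identifiers, 13752 of the named probes matched the rat RefSeq gene table of assembly GRCr8, 41 did not, and 0 symbols needed an update. The array's own genome build is not given in the sources used here, so no coordinates are printed. Among kept probes 7508 were named and 2458 unnamed, and the named ones covered 7376 genes. For gene lists, the probe with the highest mean stood for its gene. Of the genes named by the rule below, Alb and Gstp1 had more than 1 kept probe, and both probes of each lay on the same side of 0.

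Erlotinib and vehicle were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with no covariates. Unadjusted p-values in the text come from the same limma fit. Intervals are 95% confidence intervals from it. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, two-sided. The 33 lists were written before the data were examined, and 32 of them had at least 5 measured members. B and plasma cell genes, with 3, were not tested. A list score is the mean over members of the log2 intensity centred on each gene's mean over the 6 arrays. Score differences were tested with an exact permutation test, two-sided, whose smallest possible p with 3 against 3 arrays is 0.1. Figures were drawn with matplotlib 3.10.9.

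The text names genes by a rule fixed before the data were examined. It takes up to 12 genes in each direction that pass the threshold with non-overlapping groups, filled up by the smallest unadjusted p with non-overlapping groups where fewer pass. It adds 19 genes fixed by name, 4 members of each list that passed, moving with the list, and 2 members of smallest p for other lists described. Genes chosen after their values were seen are marked as such.

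The fit was tested on simulated data. With 200 of 9966 probes changed at the SDs of these arrays, 9.85% of 2-fold and 62.95% of 4-fold changes were recovered (20 runs, 100 probes of each size in a run), and on average 3.95 of 76.75 calls a run were false. The list test was checked on 5000 simulated genes in lists of 30. With independent genes and no shift, 5% of lists had a p under 0.05 at the preset correlation. With a correlation of 0.4 between genes this share was 58% at the preset and 6.5% with the correlation estimated. With that correlation and a true shift of 0.7 on the log2 scale, 86% of shifted lists were found at the preset and 34% with the correlation estimated. With independent genes and the same shift these shares were 100% and 98%. The median correlation estimated for the real lists was 0.377.

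Alternatives chosen before the data were examined were no background correction, median scaling, the authors' deposited intensities, no filter and a stricter filter on dim probes, an intensity trend or robust variances in eBayes, array weights, an estimated correlation, the fry test, the mean of all probes of a gene, other thresholds, and leaving out each array. Added after seeing the data were limma's own normexp fit with an offset of 50, median scaling over all probes, and leaving out erlotinib 2 and vehicle 1 together. The number of arrays limits the precision of every comparison.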

Results

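Expression of 9966 probes above background was compared between liver tissues of 3 DEN-exposed rats given erlotinib and 3 given vehicle, named erlotinib 1 to 3 and vehicle 1 to 3. The labels name the tissue both as hepatocellular carcinoma and as liver without tumour. Across the 9966 probes, which are not independent replicates, pairs of arrays had Pearson correlations from 0.894 (erlotinib 2 and vehicle 3) to 0.956 (erlotinib 3 and vehicle 2). The first principal component held 36.2% of the variance and set erlotinib 2 (score 42.1) and vehicle 1 (34.5) apart from the other 4 arrays, which lay between -35.3 and -8.58. On the second component, with 21.8%, the erlotinib arrays lay between -39.1 and -1.93 and the vehicle arrays between 2.90 and 27.7, a separation that chance gives to 10% of measures with 3 against 3 arrays.

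**Figure D1:**
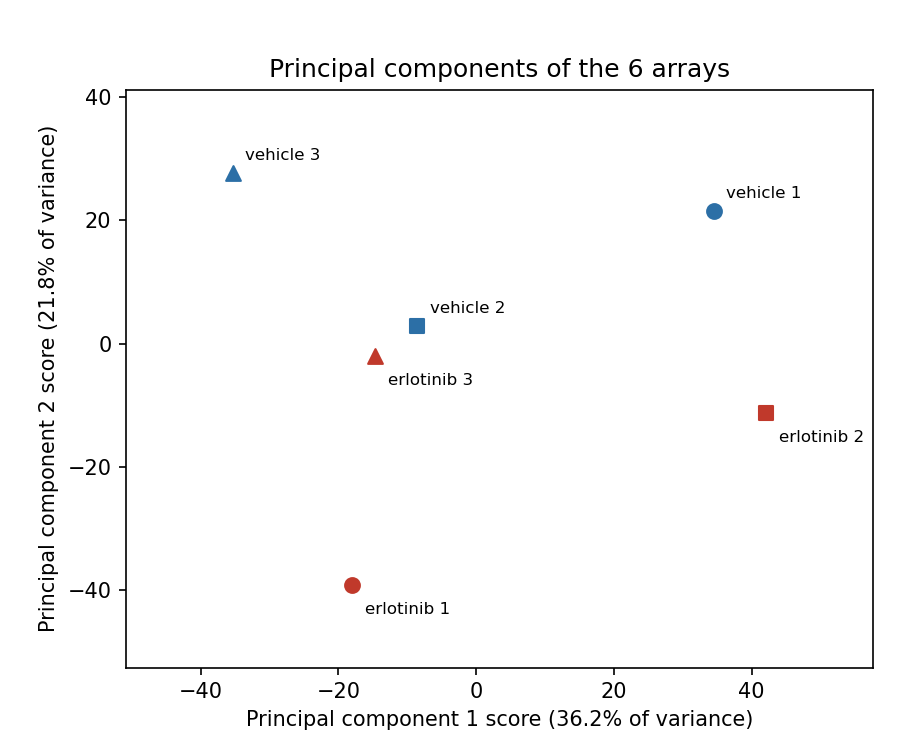
Principal component scores (unitless) of the 6 arrays over 9966 probes, 1 point per array, coloured by group. Erlotinib 2 and vehicle 1 have scores of 42.1 and 34.5 on the first component, and erlotinib 1 has the lowest score, -39.1, on the second.

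The comparison of erlotinib with vehicle addresses how giving the EGFR inhibitor in weeks 13 to 18 of DEN exposure goes with expression in these tissues. Extracellular matrix and stellate cell genes, which encode collagens and other products of the fibre-forming cells of the liver, were higher with erlotinib for 38 of 39 measured members. Genes of the urea cycle and periportal amino acid breakdown (27 of 32 lower), cholesterol synthesis (14 of 19 lower), fatty acid oxidation (26 of 32 lower) and bile duct and progenitor cells (12 of 16 lower) were mostly lower. Cell cycle genes were mostly higher (33 of 43). These 6 lists, 2 higher and 4 lower, passed camera at the preset correlation, and 0 passed with an estimated correlation (smallest adjusted p = 0.973 over the 32 lists, smallest unadjusted p = 0.0761) or with fry (smallest adjusted p = 0.953). Every other split of the arrays into 3 and 3 called more lists at the preset correlation, from 9 to 19. No member of any of the 33 lists passed the limma test, adjusted over all genes or adjusted over the list alone.

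Among single genes with non-overlapping groups and the smallest p, the erlotinib tissues had higher intensities of Reln, a secreted glycoprotein made by stellate cells (log2 difference 1.18, 95% interval 0.55 to 1.80), of the ribosomal protein gene Rps12 (1.39, 0.62 to 2.16), and of Calu, which encodes a calcium-binding protein of the secretory pathway (1.26, 0.61 to 1.90). Idh2, the mitochondrial NADP-dependent isocitrate dehydrogenase, differed by 1.04 (0.45 to 1.62), the splicing factor gene Prpf19 by 1.07, the phosphoinositide phosphatase gene Inppl1 by 1.24, the nuclear import factor gene Hikeshi by 0.94, and Nsf, an ATPase of vesicle fusion, by 0.90. Eml2 (1.27), Qars1 (1.05) and Cdr2 (1.0) were above background on 3 erlotinib and 2 vehicle arrays, and Ttc17 (1.0) on 3 and 1. In the other direction, Aqp7, a glycerol channel gene, was at 4.98 ± 0.59 with erlotinib and 6.72 ± 0.66 with vehicle (SD, n = 3), a log2 difference of -1.74 (-2.73 to -0.76). Scnn1a, a subunit of the epithelial sodium channel, differed by -1.10 (-1.78 to -0.41), Rab14, a small GTPase of endosomal traffic, by -1.06, and the proteasome assembly gene Psmd9 by -1.03. Zc3h11a (-0.97), Pick1 (-0.97), Mblac1 (-0.92), Tmem222 (-0.86), Nostrin (-0.81), R3hdm4 (-0.80), Scand1 (-0.80) and the mitochondrial ribosome gene Mrps18a (-0.73) completed the set.

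None of these genes passed: 0 of 9966 probes were higher and 0 lower at an adjusted p under 0.05 in limma, and the smallest adjusted p was 0.796. At an unadjusted p under 0.05 there were 357 higher and 243 lower probes, together 600 (6.02%) where 498 are expected by chance, and no other tool was run on single probes. Other splits of the arrays into 3 and 3 gave between 133 and 889 such probes. The splits with 725, 779 and 889 exceeded the real 600, so that count is not more than arbitrary groupings can give. The groups did not overlap for 1228 probes (12.3%), where chance gives 10%. The median 95% interval reached 0.64 to either side on the log2 scale, or 1.56-fold. Without vehicle 3 the 600 probes became 317, and with median scaling over all probes, added after seeing the data, 203, of which 96 were higher and 107 lower.

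The extracellular matrix and stellate cell list had a median log2 difference of 0.61. Its score was 0.35 ± 0.86 with erlotinib and -0.35 ± 0.53 with vehicle (SD, n = 3). Col3a1, a fibrillar collagen, was 5.04-fold higher (9.36 ± 1.22 against 7.03 ± 0.59, log2 difference 2.33, interval 0.91 to 3.76), and its groups did not overlap. Lgals1, which encodes galectin-1, differed by 1.37 (0.23 to 2.51), Reln by 1.18 and the growth factor gene Tgfb2 by 0.49 (-0.05 to 1.04). Among genes fixed by name, Col1a1 differed by 1.55 (-0.76 to 3.86), Timp1, an inhibitor of matrix proteases, by 0.51 (-1.45 to 2.47) and Tgfb1 by 0.34 (-0.46 to 1.14). In single arrays Col1a1 ran from 5.94 (erlotinib 1) to 9.37 with erlotinib and from 4.71 (vehicle 3) to 7.21 with vehicle. The list passed camera with an adjusted p = 5.72e-07, and over all alternatives from 1.12e-23 to 0.973, the latter with an estimated correlation. Its unadjusted p was 1.79e-08, and 3 of the 9 other splits of the arrays into 3 and 3 gave a smaller one, down to 2.91e-28. Erlotinib 1 scored -0.64, below vehicle 1 (-0.17) and vehicle 2 (0.07), and vehicle 3 had the lowest score (-0.94). The median was 0.31 without vehicle 3, 0.35 without erlotinib 2 and 1.0 without erlotinib 1, and the list passed in each case, as it did without any other single array. It was 0.35 with no background correction, 0.36 with the authors' deposited values and 0.38 without erlotinib 2 and vehicle 1 together, and the list passed in these too.

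The cell cycle and mitosis list had a median of 0.13, with scores of 0.10 ± 0.33 and -0.10 ± 0.17 (SD, n = 3). Cks2, a subunit of cyclin-dependent kinases, differed by 0.89 (0.22 to 1.56), the spindle checkpoint kinase gene Bub1 by 0.86 (0.16 to 1.57), the replication helicase gene Mcm2 by 0.67 (-0.02 to 1.36) and the cyclin gene Ccne2 by 0.70 (-0.07 to 1.47), above background on 3 erlotinib and 2 vehicle arrays. The list's adjusted p was 0.0226, and 1.22e-05 to 0.973 over all alternatives, the latter with an estimated correlation. The median was -0.02 without erlotinib 1, 0.20 without erlotinib 2 and 0.08 without vehicle 3, and the call was lost in these cases and with the stricter filter on dim probes (0.12). It was 0.37 without erlotinib 3, 0.22 without vehicle 1 and 0.23 without vehicle 2, and 0.07 with no background correction, 0.07 with the authors' deposited values and 0.08 with limma's own normexp fit, where the list passed.

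**Figure D2:**
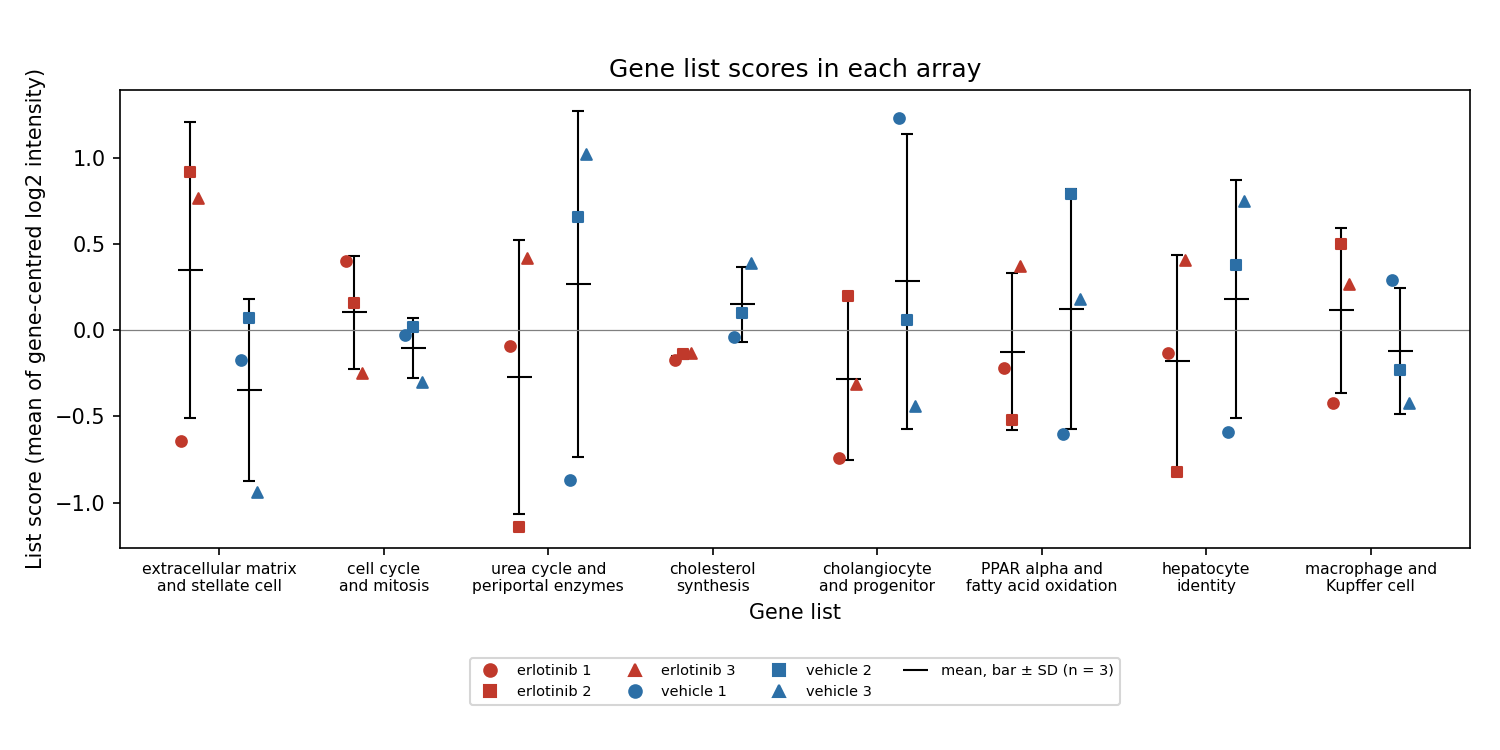
List scores (mean of gene-centred log2 intensity) of the 6 lists that passed camera and of the hepatocyte and macrophage lists in each array, with the mean and SD of the 3 arrays of each group. Cholesterol synthesis is the list whose groups do not overlap (-0.15 ± 0.02 with erlotinib, 0.15 ± 0.22 with vehicle), and for extracellular matrix genes erlotinib 1, at -0.64, lies below 2 vehicle arrays.

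Cholesterol synthesis genes had a median log2 difference of -0.32. Their scores, -0.15 ± 0.02 with erlotinib and 0.15 ± 0.22 with vehicle (SD, n = 3), did not overlap (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 arrays allow, reached by 1 of 32 lists). Chance gives that smallest p to 10% of measures. For the other lists that passed camera, the exact permutation p was 0.3 (extracellular matrix), 0.4 (cell cycle), 0.5 (urea cycle), 0.5 (cholangiocyte) and 0.7 (fatty acid oxidation). Sqle, a rate-controlling epoxidase of sterol synthesis, differed by -0.89 (-1.59 to -0.20). Mvd, of the mevalonate part of the pathway, differed by -0.68 (-1.36 to 0.00), Stard4, a sterol carrier, by -0.81 (-1.77 to 0.15) and Sc5d, a late desaturase, by -0.49 (-1.12 to 0.14). The adjusted p was 0.0226, and 0.00138 to 0.973 over all alternatives, the latter with an estimated correlation. The median was -0.14 without erlotinib 2, -0.10 with no background correction, -0.12 with the authors' deposited values and -0.16 with limma's own normexp fit, with the call kept in each, and -0.08 without vehicle 3, where it was lost, as it also was with no filter on dim probes (-0.29).

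Urea cycle and periportal genes had a median of -0.48, with scores of -0.27 ± 0.80 and 0.27 ± 1.0 (SD, n = 3) and an adjusted p of 0.0157. Over all alternatives the adjusted p ran from 4.91e-10 to 0.973, the latter with an estimated correlation. The 4 lower members of smallest p belong to other steps than the urea cycle: Hpd, of tyrosine breakdown (-1.67, -4.15 to 0.81), Pck1, of gluconeogenesis (-1.40, -3.61 to 0.82), Sdsl, a serine dehydratase-like enzyme (-0.92, -2.10 to 0.25), and Haao, of tryptophan breakdown (-0.85, -2.19 to 0.49). Erlotinib 2 (-1.14) and vehicle 1 (-0.87), apart on the first principal component, had the lowest scores of this list, and also of the hepatocyte identity list (-0.82 and -0.59), with which it shares 6 measured genes, Hpd and Pck1 among them. The 26 hepatocyte identity genes outside it shifted by -0.28, and the urea cycle list by 0.26 more in the same direction (standard error 0.28), with overlapping groups. The median was -0.19 without erlotinib 2, -0.27 without vehicle 2 and -0.14 without vehicle 3, where the call was lost, and -0.91 without erlotinib 3 and -1.08 without vehicle 1, where the list passed.

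Targets of peroxisome proliferator-activated receptor alpha and genes of fatty acid oxidation had a median of -0.26, with scores of -0.12 ± 0.45 and 0.12 ± 0.70 (SD, n = 3). Hadha, a subunit of the mitochondrial trifunctional protein, differed by -0.77 (-1.39 to -0.15), the acylcarnitine carrier gene Slc25a20 by -0.68 (-1.31 to -0.06), Crat by -0.53 (-1.05 to -0.02) and Cpt2, both carnitine acyltransferases, by -0.65 (-1.44 to 0.13). The adjusted p was 0.0329, and 2.31e-07 to 0.973 over all alternatives, the latter with an estimated correlation. Vehicle 1 (-0.60) and erlotinib 2 (-0.52) had the lowest scores of this list too, and the list's shift was smaller than that of the 32 hepatocyte identity genes, of which it holds 0, by 0.12 (standard error 0.31), with overlapping groups. The call was lost without erlotinib 1 (median -0.29), erlotinib 2 (-0.02), vehicle 2 (-0.01) or vehicle 3 (-0.24), with no background correction (-0.16), the authors' deposited values (-0.17) and the stricter filter (-0.19), and the median was -0.45 without erlotinib 3 and -0.52 without vehicle 1.

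Cholangiocyte and progenitor cell genes had a median of -0.58, with scores of -0.28 ± 0.47 and 0.28 ± 0.86 (SD, n = 3). Onecut1, a transcription factor of liver and bile duct development, was 3.87-fold lower (6.53 ± 0.83 against 8.49 ± 0.92, log2 difference -1.95, interval -3.27 to -0.64), with non-overlapping groups. Sox4 differed by -1.25 (-2.33 to -0.18), the tight junction gene Cldn4 by -1.47 (-2.85 to -0.10) and Prom1, a progenitor surface marker, by -1.16 (-2.45 to 0.14). The adjusted p was 0.0226, and 7.05e-06 to 0.973 over all alternatives, the latter with an estimated correlation. Vehicle 1 had the highest score (1.23): without it the median was 0.27 and the call was lost, as it was without erlotinib 1 (-0.40), without erlotinib 2 and vehicle 1 together (-0.10), with no background correction (-0.41), the authors' deposited values (-0.43), no filter (-0.41), the stricter filter (-0.29) and limma's own normexp fit (-0.50). Without vehicle 3 it was -1.09, and the list passed. Vehicle 1 also had the highest intensities of genes typical of stomach and intestinal epithelium, picked after their values were seen: Tff1, itself a member of this list (9.47, against at most 8.06 elsewhere), Agr2 (11.45, at most 6.19) and Krt20 (10.47, at most 8.80).

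**Figure D3:**
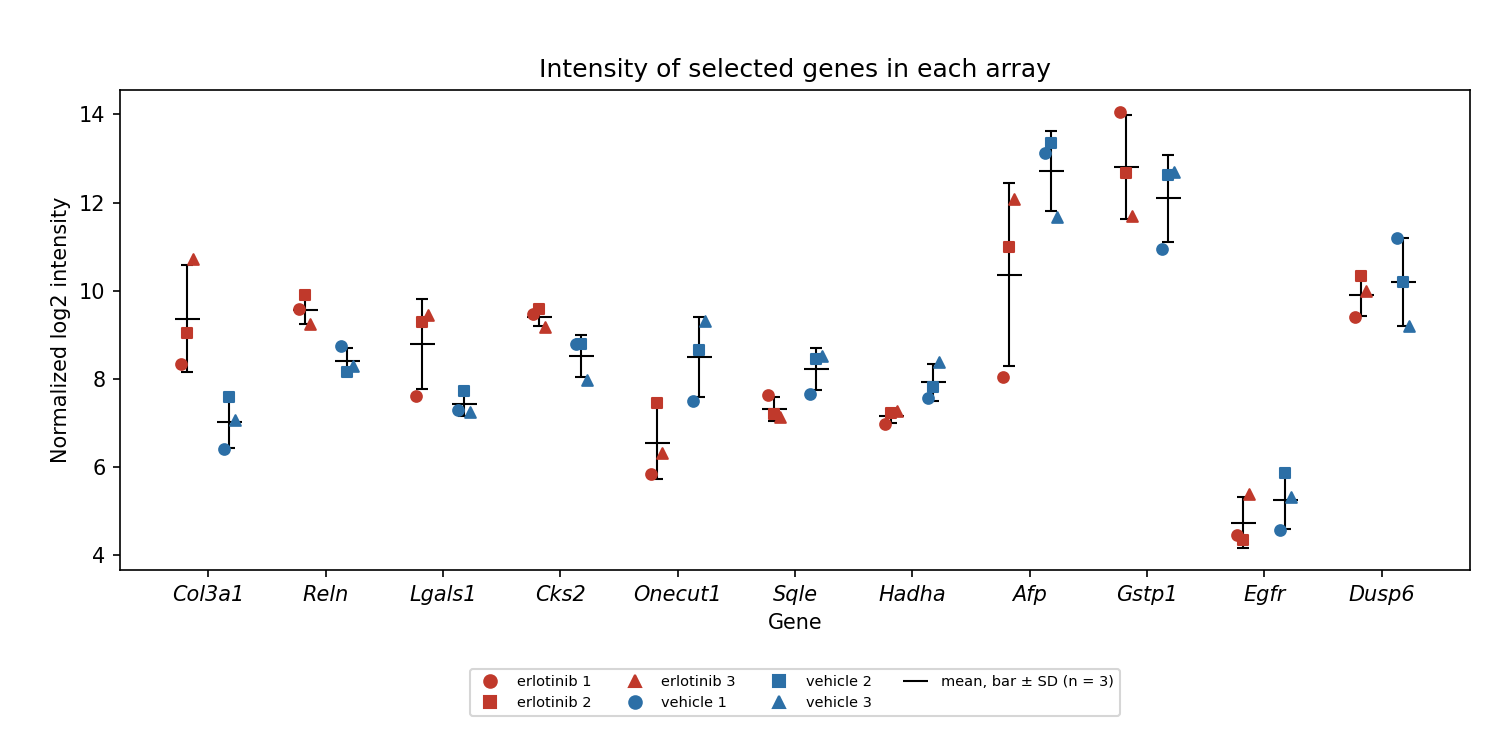
Normalized log2 intensity of 11 genes in each array, with the mean and SD of the 3 arrays of each group. Col3a1 is at 9.36 ± 1.22 with erlotinib and 7.03 ± 0.59 with vehicle, Onecut1 at 6.53 ± 0.83 and 8.49 ± 0.92, and Afp runs from 8.04 to 12.07 among the erlotinib arrays.

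Egfr itself, which encodes the target of the drug, was near background. It stood at 4.73 ± 0.57 with erlotinib and 5.24 ± 0.65 with vehicle (SD, n = 3) and was above background on 1 erlotinib and 3 vehicle arrays (difference -0.52, interval -1.49 to 0.45). Of the EGFR family receptors and ligands, 5 were measured, 2 higher and 3 lower (median -0.28, adjusted p = 0.607). Egf differed by -0.52 (-1.15 to 0.11), on 2 erlotinib and 3 vehicle arrays above background. Erbb3 differed by 0.29 (-0.17 to 0.76) and Hbegf by 0.13 (-0.48 to 0.74), each on 3 and 2 arrays, and Tgfa by -0.28 (-1.01 to 0.46). Erbb2, Areg and Spry4 were not above background on 3 arrays, and Mki67 and Acta2 are not analysed here. Output genes of the ERK pathway, which EGFR feeds, were higher for 10 and lower for 10 of 20 (adjusted p = 0.665). Erlotinib was given in weeks 13 to 18 and tissue was taken in week 19. These values therefore do not show ERK output during dosing. Dusp6, a feedback phosphatase of ERK, differed by -0.29 (-1.47 to 0.90), Egr1 by -0.13 (-1.09 to 0.84) and Ccnd1 by 0.11 (-0.93 to 1.14), and the members of smallest p were Mcl1 (0.59, -0.06 to 1.24) and Phlda1 (1.01, -0.17 to 2.20, above background on 3 erlotinib and 2 vehicle arrays).

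Markers of rat liver tumours and preneoplastic foci were higher for 12 and lower for 10 of 22 (adjusted p = 0.695). The list's median was 0.10 and its mean -0.33, with a downward camera direction, and over the alternatives the median ran from -0.24 to 0.17. Afp, the fetal serum protein that many liver tumours express, was at 10.4 ± 2.08 with erlotinib and 12.7 ± 0.91 with vehicle (SD, n = 3), a log2 difference of -2.35 (-4.68 to -0.03), and among the erlotinib arrays it ran from 8.04 in erlotinib 1 to 12.07 in erlotinib 3. Gpx2, a glutathione peroxidase, differed by -1.89 (-3.80 to 0.02), the oncofetal proteoglycan gene Gpc3 by -1.10 (-3.23 to 1.02) and Gstp1, the classical marker of rat preneoplastic foci, by 0.72 (-0.89 to 2.33). The differences of Afp, Gpc3 and Gstp1 lean on erlotinib 1. Afp was at 8.04 there, against 10.98 and 12.07 in erlotinib 2 and 3. Gpc3 was at 6.87, against 9.70 and 9.19, and Gstp1 at 14.06, against 12.68 and 11.70. Of the 2 probes for albumin (Alb), the brighter read 86.1% to 99.2% of the array maximum, too near the top of the scale to measure a difference (0.06, -0.38 to 0.50). The dimmer was at 12.29 with erlotinib and 12.05 with vehicle, a difference of 0.24 (-0.51 to 1.0).

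With all arrays and the main settings, lists of other cell types gave no further calls. Macrophage and Kupffer cell genes were higher for 16 of 23 (median 0.34, adjusted p = 0.0541), with the scavenger receptor gene Cd163 at 0.77 (0.19 to 1.35) and the oxidase gene Cybb at 0.85 (-0.02 to 1.72). This list passed in 6 of 19 alternatives: without erlotinib 1 (median 0.53), vehicle 1 (0.49) or erlotinib 2 and vehicle 1 together (0.31), with no filter (0.28), the stricter filter (0.35) and array weights (0.29). Without erlotinib 2 its median was 0.02. Endothelial genes were higher for 11 of 14 (median 0.23, adjusted p = 0.111). Sox18 differed by 1.20 (0.34 to 2.06), above background on 3 erlotinib and 1 vehicle arrays, and Sox17 by 0.50 (-0.11 to 1.10), on 3 and 2. The endothelial list passed in 3 of 19 alternatives, without erlotinib 1 (0.50) or vehicle 2 (0.53) and with median scaling over all probes (0.20), and its median was -0.12 without erlotinib 2 and vehicle 1 together. Hepatocyte identity genes were lower for 23 of 32 (median -0.26, adjusted p = 0.115), with Ttr, for transthyretin, at -0.50 (-1.17 to 0.17) and Hpd at -1.67. They passed in 5 of 19 alternatives, without erlotinib 3 (-0.51), vehicle 1 (-0.60) or erlotinib 2 and vehicle 1 together (-0.31), with array weights (-0.34) and with median scaling over all probes (-0.29), and the median was 0.05 without erlotinib 2. Cytochrome P450 genes were lower for 18 of 24 (median -0.26, adjusted p = 0.115), with Cyp2d1 at -0.53 (-1.04 to -0.02) and Cyp2c11 at 1.27 (-0.51 to 3.05), above background on 3 erlotinib and 1 vehicle arrays. These passed in 4 of 19 alternatives, without erlotinib 3 (-0.73) or vehicle 1 (-0.40), with array weights (-0.36) and with median scaling over all probes (-0.30), and the median was 0.15 without erlotinib 2. The adjusted p was 0.13 for T and NK cell genes, 0.751 for neutrophil and mast cell genes, 0.785 for erythrocyte genes and 0.994 for genes of MHC class II. T and NK cell genes passed without erlotinib 2 (-0.44) or vehicle 2 (-0.37), and neutrophil and mast cell genes without erlotinib 1 (0.60).

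Inflammatory cytokine and chemokine genes were higher for 19 of 28 (median 0.25, adjusted p = 0.115). The chemokine genes Ccl2, above background on 3 erlotinib and 2 vehicle arrays, and Cxcl1 differed by 1.77 (0.29 to 3.24) and 1.88 (0.11 to 3.64). For Cxcl1, vehicle 3 was at 6.45, against 9.58 and 9.00 in vehicle 1 and 2 and 9.89 to 10.61 with erlotinib. The list passed without erlotinib 1 (0.44) or vehicle 1 (0.51), and its median was -0.03 without erlotinib 2. Genes of glycolysis and hypoxia were higher for 17 of 26 (median 0.20, adjusted p = 0.115), with the hexokinase gene Hk2 at 1.29 (0.45 to 2.13) and the collagen hydroxylase gene P4ha2 at 0.93 (0.16 to 1.70), each on 3 and 2 arrays, and that list passed without erlotinib 1 (0.20). In the insulin-like growth factor axis (7 higher, 8 lower, adjusted p = 0.722), Igf2r differed by 0.96 (0.36 to 1.56) and Igfbp7 by 0.94 (-0.13 to 2.01). The largest difference in that list, picked after its value was seen, was that of Igf2 (-2.92, -6.47 to 0.63). Igf2 was at 5.42 in erlotinib 1, against 10.99 and 11.74 in erlotinib 2 and 3. That list had a median of -0.04 and a mean of -0.13 with an upward camera direction, and over the alternatives the median ran from -0.24 to 0.16. Among NRF2 targets and glutathione enzymes (adjusted p = 0.766), Hmox1 differed by 0.92 (-0.37 to 2.22) and Gsr by 0.93 (-0.56 to 2.42). Those genes passed in opposite directions without erlotinib 1 (median -0.44) and without erlotinib 2 (0.54). Ribosomal protein genes (29 higher, 27 lower, adjusted p = 0.366) included Rps12 and Rps26 (1.15, 0.49 to 1.81).

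The adjusted p of the remaining lists was 0.102 for p53 targets, 0.19 for oxidative phosphorylation subunits, 0.351 for epithelial junction and mesenchymal transition genes, and 0.366 each for acute phase genes and bile acid synthesis and transport. It was 0.556 for interferon response genes, 0.607 for the unfolded protein and integrated stress response, 0.785 each for fatty acid synthesis and pericentral genes, and 0.959 for male-biased genes. The median and mean differed in sign for erythrocyte genes (0.10 and -0.09) and male-biased genes (0.02 and -0.02), whose medians ran from -0.53 to 0.23 and from -1.12 to 1.03 over the alternatives. With 1 array left out, male-biased genes passed without erlotinib 2 (1.03; 0.97 without vehicle 1 as well) and, the other way, without erlotinib 3 (-1.12), and acute phase genes without erlotinib 1 (0.28) and, the other way, without erlotinib 3 (-0.48). Bile acid genes passed without erlotinib 3 (-0.61) or vehicle 1 (-0.54), p53 targets without erlotinib 3 (-0.33) or vehicle 1 (-0.45), pericentral genes without erlotinib 3 (-0.51), oxidative phosphorylation subunits without erlotinib 1 (-0.28) and interferon response genes without vehicle 2 (-0.26). With all arrays, p53 targets and oxidative phosphorylation subunits also passed in 2 alternatives each.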

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

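The counts of 0 probes higher and 0 lower held under every alternative run, leaving out any single array included, except the looser threshold of an unadjusted p under 0.01 with at least a 1.5-fold difference, which by its construction took 65 higher and 31 lower probes. The 6 lists became 10 with array weights, 11 with median scaling over all probes (added after seeing the data), and 0 with an estimated correlation or fry. They were 2 (without vehicle 3) to 13 (without erlotinib 3) when 1 array was left out, 11 without erlotinib 1 or vehicle 1, and 8 without erlotinib 2 and vehicle 1 together. The extracellular matrix list passed in 17 of 19 alternatives, the exceptions being the estimated correlation and fry. All 17 used the preset correlation of 0.01, where 0.561 was estimated for this list, so they do not test that preset. The list was higher in all 19, but 3 of the 9 other splits of the arrays gave it a smaller p than the real one. The cause was not tested. In simulated lists with a correlation of 0.4, the preset test called 58% of unshifted lists, and the estimated correlation found 34% of shifted ones. At such a correlation a preset call does not by itself show a shift, and its loss under the estimate does not exclude one. Among the lists that passed, the estimated correlation was 0.37 to 0.561, but 0.046 for cholesterol synthesis, which that simulation does not cover. With independent genes and a shift of 0.7, the estimated correlation found 98% of shifted lists. The mean difference of cholesterol synthesis was smaller, at -0.30. At an unadjusted p under 0.05, the 357 higher and 243 lower probes became 96 and 107 with median scaling over all probes, and no scaling moved the median probe by over 0.1 on the log2 scale.

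The log2 difference of Alb was -0.04 with the authors' deposited values. With no filter the median of the EGFR family list was 0.01, and with the stricter filter that of inflammatory genes was -0.02, of tumour markers -0.24, of erythrocyte genes -0.21 and of male-biased genes -0.08. Array weights gave -0.07 for tumour markers, -0.15 for male-biased genes and 0.03 for the insulin-like growth factor axis. The last was at 0.13 with median scaling and 0.11 with median scaling over all probes, where male-biased genes were at -0.02 and -0.04. Without erlotinib 2 and vehicle 1 together, Tgfa was at 0.09, the EGFR family median at 0.03, the endothelial median at -0.12, tumour markers at -0.20, erythrocyte genes at -0.53 and the insulin-like growth factor axis at 0.10. Leaving out 1 array, differences ran from -0.14 to 0.55 for Ccnd1, -0.77 to 0.21 for Dusp6, -0.41 to 0.23 for Egr1, -0.09 to 0.27 for Hbegf and -0.27 to 1.24 for Timp1. Medians ran from -0.02 to 0.37 for cell cycle, -1.09 to 0.27 for cholangiocyte, -0.73 to 0.15 for cytochrome P450, -0.60 to 0.05 for hepatocyte, -0.03 to 0.51 for inflammatory, -0.41 to 0.23 for erythrocyte and -1.12 to 1.03 for male-biased genes, -0.13 to 0.17 for tumour markers and -0.11 to 0.16 for the insulin-like growth factor axis. The cause was not tested. Of the other values of single genes under the alternatives, 1341 kept their sign. No probe passed in any of these alternatives, so no gene could change its side of the threshold. Many of these genes were picked from the same data for a small p, and the count does not cover changes in size. It is therefore no measure of robustness.

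No paired analysis was possible because the labels give the groups no shared replicate numbers. The robust variance setting has no counterpart in the list test and was run on probes alone. Probes that left the filter in an alternative have no value there. Signal over background limits Egfr and other dim genes, which lie close to the offset.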

Other observations

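The tests of hepatocyte share, of single arrays, of signal strength, of gastrointestinal genes in vehicle 1 alone and of other splits were chosen only after their results were seen, whereas that of gastrointestinal genes in erlotinib 2 and vehicle 1 together was set before its result. The bounds for single arrays, signal strength and vehicle 1 alone were also tightened with their values known. The individual tissues differed in programmes that do not follow the groups. The genes named here were chosen after their values were seen. Erlotinib 1 had the lowest log2 intensity of Igf2, the fetal growth factor (5.42, against 10.99 to 12.83 in the other 5 arrays), and of Afp (8.04, against 10.98 to 13.36), with the highest Gstp1 (14.06) and Aldh3a1 (9.12, against at most 6.57). Its score for NRF2 targets and glutathione enzymes was 1.08, the highest of the 6. Vehicle 1 (-0.98) and erlotinib 2 (-0.92) had the lowest. Erlotinib 3 had the highest score for male-biased liver genes (1.95) and was alone in a clear signal of Cyp2c11, the main male-specific cytochrome P450 of rat liver (7.64, against at most 4.75), while erlotinib 2 had the lowest male-biased score (-1.77).

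Several transcripts typical of stomach and intestinal epithelium were high in vehicle 1, and some of them in erlotinib 2. The secreted trefoil factor gene Tff3 was at 11.50 in vehicle 1 and 11.47 in erlotinib 2, against at most 8.64 elsewhere, and Tff1 at 9.47 and 8.06, against at most 5.51. Lypd8 was at 12.87 and 10.27, but also at 9.47 in vehicle 2. Other such genes did not set erlotinib 2 apart: Cdh17 was at 11.31 in vehicle 1 and 10.65 in erlotinib 2, but at 10.44 in vehicle 2 and 9.65 in erlotinib 1, Lgals2 at 12.13 and 10.60, but at 10.41 in vehicle 2, and Lgals4 at 11.57 and 8.97, but at 9.63 in erlotinib 1. The antimicrobial lectin gene Reg3b reached 10.88 in vehicle 1 and 6.14 in erlotinib 2, whereas Reg4 reached 8.74 in erlotinib 2 and 6.27 in vehicle 1. Among further markers of such epithelium, Agr2 was at 11.45 in vehicle 1, against at most 6.19 elsewhere, and Tff2 at 9.20 in vehicle 1 and 8.02 in erlotinib 2, against at most 4.32 elsewhere. Others were not highest in vehicle 1: Lgals3 was at 12.22 there and 12.40 in erlotinib 2, Ctse at 7.81 and 8.05 in erlotinib 1, and Cdhr5 at 6.92, against 7.96 in vehicle 3 and 7.39 in erlotinib 1. The same 2 arrays had the lowest hepatocyte identity scores (-0.82 in erlotinib 2 and -0.59 in vehicle 1).

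For the first pattern, erlotinib 2 and vehicle 1 standing apart on the first principal component, a hypothesis is that these tissues held epithelium of gastrointestinal type, which was tested on 49 further marker genes, of which 19 were above background on at least 2 arrays (8 of them on all 6, and 2 are in another list). The smaller of the 2 arrays' medians exceeded the highest of the other 4 arrays by 0.17 on the log2 scale. Erlotinib 2 lay 0.41 above the median of those 4, under the bound of 0.5 written beforehand. The standard error of its own median over the 19 genes was 0.22. That error takes the genes of an array as independent and leaves out the error of the other 4 arrays, so it is not the error of the 0.41. The 0.41 lay under the bound by less than that error, a criterion on the spread applied after the value was seen, so the question stays open. For vehicle 1 alone the excess was 1.16 with a standard error of 0.42 for its median, but keeping genes above background on at least 2 arrays favours arrays in which they are high, and the excess was 0.64 (standard error 0.42) over the 8 genes above background on all 6 arrays and 0.65 over all 31 with a probe (-0.32 and 0.04 for erlotinib 2), so epithelium in vehicle 1 alone stays open as well. Signal strength stays open too: erlotinib 1 and erlotinib 2, nearest in raw mean intensity (271 and 268), lay 77.6% of the range apart, which argues against it, but erlotinib 2 and vehicle 1 also had the most probes above background (10266 and 10260).

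The second pattern is the higher extracellular matrix list with erlotinib beside the lower urea cycle and fatty acid oxidation lists, for which a lower share of hepatocytes may raise the genes of every other cell type and lower those of hepatocytes. The matrix list shifted by 0.76 more than the mean of the bile duct, macrophage, T and NK, and endothelial lists, which shifted by -0.06, but the standard error was 0.43 and the groups overlapped, so a lower hepatocyte share cannot be told apart from a matrix change. That -0.06 averages opposite mean shifts: macrophage 0.24 and endothelial 0.28, against bile duct -0.56 and T and NK -0.20. Without vehicle 1 the median of the bile duct list turned to 0.27. The urea cycle list minus the hepatocyte identity genes outside it shifted by -0.26 (standard error 0.28), and the fatty acid oxidation list minus the hepatocyte identity genes by 0.12 (standard error 0.31), with overlapping groups in both, while the hepatocyte genes themselves shifted by -0.28 (standard error 0.48) and -0.36 (0.53), so a lower hepatocyte share stays open for these lists too. Over the 6 arrays, the Pearson correlation with those hepatocyte genes was 0.98 for the urea cycle list and 0.83 for the fatty acid oxidation list. The hepatocyte identity list holds the brighter Alb probe, which is too near the top of the scale to measure a difference. It also holds Tf, brighter still at 14.40 with erlotinib and 14.37 with vehicle. The shift of the hepatocyte list may therefore be understated. Whether 1 array decides the matrix shift is also open: the difference of the list's mean was 0.69 with all arrays and 0.40 without vehicle 3, with a standard error of 0.51. Erlotinib itself, and the tumour or non-tumour origin of each tissue, remain as untested biological explanations. Per the labels, vehicle animals of separate erlotinib studies were pooled, and the study of each vehicle rat is not named. A difference between studies could therefore not be tested or told apart from the groups.

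The third pattern is the count of gene lists. All 10 splits of the 6 arrays into 3 and 3, the real one included, called at least as many lists as the real split: 6 there and 9 to 19 in the others. The real split thus called the fewest, and its count is not more than arbitrary groupings of these arrays give. For the extracellular matrix list, 4 of the 10 splits, the real one included, gave a camera p at least as small as the real 1.79e-08, and the smallest other was 2.91e-28. With 10 splits no share under 0.05 can be reached. The real count of single probes was 0, which every split reaches by definition, so it tests nothing, and the highest other split called 1.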
